A study of Mus musculus with 5 samples.

How the data were processed

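RNA bound to an anti-Staufen1 antibody was measured by sequencing (RIP-seq) in quiescent muscle stem cells (MuSCs) of the mouse. Staufen1 is a protein that binds double-stranded RNA. The titles place 3 libraries in the wild type group and 2 in the Staufen knockout group, and all 5 libraries were immunoprecipitates. Per the labels' protocols, the precipitated RNA was copied with oligo(dT) priming and amplified before library preparation, and was sequenced as paired-end 101 bp reads. No input RNA library was used here, so a difference in the amount of a transcript in the cells and a difference in its recovery by the antibody enter the same count. The labels do not say whether the libraries of a group came from separate animals. All p-values therefore measure only the spread between these samples, which may be technical.

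Per the submitters' processing notes, Trim Galore, STAR, featureCounts from Subread and edgeR were used, with the mm10 genome. Versions, the annotation release and the strand setting are not given in the sources used here. Genes that overlap on either strand are therefore uncertain. Overlaps were looked up for the genes named by the rule below, and not for the further list members named in the text. Besides the overlaps given with the genes of largest change, Egfl7 overlaps Agpat2, Ccnd1 overlaps LTO1, Hspa5 overlaps Rabepk and Mylpf overlaps Septin1. Rpl12 overlaps Lrsam1, Colgalt1 overlaps Unc13a and Hbb-b1 overlaps Hbb-bs. Srpx, Alg9, Fam117b, Pde9a, Casq1, Peli2, Me1, Pdia4, Flt1, Ly6a, Mbp, ND1, Snhg20 and Isg15 overlap noncoding genes or pseudogenes. The deposited table holds raw counts per gene, in whole numbers, with a gene length in bases and gene coordinates. It covers 11194 genes. The table had been filtered on expression before deposit, as its values show: the third-highest CPM (the count of a gene scaled to a common library total) of a gene across the 5 libraries was never below 3.02. A gene present only in both knockout libraries could not pass such a filter, which limits what can be found higher in knockout, and library totals cover the kept genes only. A symbol was given for 10826 genes and none for 368. Of the 10826 Entrez identifiers, 10824 matched the RefSeq gene table of the same assembly. 18 symbols that spreadsheet software had turned into dates were restored through that match. Genes with no symbol are described only by the RefSeq genes they overlap.

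Counts were analysed as deposited in R 4.3.3 with edgeR 4.0.16: filterByExpr, TMM scaling, estimateDisp, glmQLFit and the two-sided quasi-likelihood F-test for genotype, with Benjamini-Hochberg adjustment and a threshold of 0.05. The filter removed no gene. Log2 fold changes are wild type over knockout, each with a standard error taken from the fitted coefficient and its F statistic. The test had 14 degrees of freedom, of which 11 came from the prior that pools the spread across genes. CPM values are on TMM-scaled library sizes and are given as mean ± SD. Library totals ran from 3091302 to 105473455 counts, and the deepest library was 34.1 times the shallowest. Knockout 2, the shallowest, had 522 genes under 10 counts and 14 at 0, against 0 and 0 in wild type 1. A count of 0 allows up to 0.971 CPM in knockout 2 and up to 0.0284 CPM in wild type 1, taking 3 counts as the upper limit. Such limits, and the 95% exact intervals of count ratios, cover counting error only, since the protocol names no molecular identifiers. Replicates of a group differed by more than sampling noise: the chi-square per degree of freedom over genes was between 17.7 and 258.5 for the 4 pairs.

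Before the data were examined, 28 gene lists, the designs, the processing alternatives and the rule for named genes were fixed. The rule names Stau1 and Myod1; per direction, the 12 genes with the largest log2 fold change among those past the threshold, with at least 5 CPM in the higher group and libraries that do not overlap between groups, leaving out predicted or unnamed gene models; and per list the 3 members with the smallest p. It left out 0 unnamed genes higher in wild type and 2 higher in knockout. Lists were tested with camera from limma 3.58.1, a competitive two-sided test, with a preset inter-gene correlation of 0.01 and then with a correlation estimated per list, with Benjamini-Hochberg adjustment over the lists. With an estimated correlation, camera also takes its degrees of freedom from the 5 libraries, so that test is hard to pass at any correlation. For myogenic regulators, whose estimated correlation was -0.023, camera's unadjusted p still rose from 0.0041 to 0.0531. A list that fails it has therefore not been shown to fail because its members vary together. The lists were also tested with fry, which tests whether the members of a list move on balance in 1 direction. The 28 lists covered myogenic regulators, muscle stem cell quiescence, immediate early genes, cell cycle, Staufen1 targets from other systems, Staufen proteins with decay factors and RNA granules, endoplasmic reticulum folding, extracellular matrix, the Notch pathway, translation factors, nuclear long noncoding RNAs, muscle fibre, 7 further cell types, Y-linked genes, and gene families matched by symbol. The pattern fixed for mitochondrially encoded genes matched 0 symbols, because the table writes them without the usual prefix, so the 9 genes on the mitochondrial chromosome were taken instead.

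The edgeR and camera steps were tested on simulated data: counts were drawn for the 11194 genes of this comparison with 200 genes changed, in 5 simulations. The test recovered 6.7% of genes changed 1.5-fold, 43.4% of those changed 2-fold and 90.2% of those changed 4-fold, and 3.2% of its calls were false. Simulated genes of the same level were given the same spread between libraries, taken from the fitted trend. The spread of real genes also differs from gene to gene, so these percentages need not hold for the data. A list raised in the simulation was called in 5 of 5 runs with either correlation. An unchanged list was called in 0 with the preset correlation. These calls carried no adjustment over the planned lists, so they do not show how often the estimated correlation passes after it. In the data, camera's unadjusted p with an estimated correlation was 0.0162 for the matrix list and 0.019 for the quiescence list. After adjustment both were 0.266. Simulated genes varied independently of each other, whereas the estimated correlation was, for example, 0.576 for the list of endothelial genes. These runs therefore do not show how often the preset correlation calls unchanged lists whose members vary together.

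Alternatives covered RLE size factors, total counts without TMM factors, upper-quartile factors, no filter and a stricter filter on low counts (5 CPM in 2 libraries), DESeq2 1.42.0, limma-voom with sample weights, the edgeR exact test, a test against a 1.5-fold change, the replicate number as a block, and each library left out in turn. Thinning every library to the depth of the shallowest was added after the data were seen, as were 4 further gene lists used only in the closing section. Figures were drawn with matplotlib 3.10.9.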

Results

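The data are counts per gene from 5 anti-Staufen1 immunoprecipitates of mouse muscle stem cells, the resident precursors of skeletal muscle, kept quiescent. 3 libraries were labelled wild type and 2 were labelled Staufen knockout. Totals were 105473455, 33846391 and 70042508 counts in wild type 1 to 3, and 9370244 and 3091302 counts in knockout 1 and 2, so every knockout library was shallower than every wild type library. Log2 CPM values correlated at 0.970 to 0.972 across genes between the wild type libraries and at 0.937 between the knockout libraries. Between groups the correlations were 0.917 to 0.952, and genes are not independent replicates. The comparison asked which transcripts are recovered with Staufen1, taking the knockout immunoprecipitate as background, and the series title singles out the transcript of MyoD.

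The targeted gene was examined first, because it checks the labels. Stau1 (chromosome 2, 166947549 to 166996299, minus strand, mm10) had 104.3, 126.8 and 118.2 CPM in the libraries labelled wild type and 109.0 and 110.7 CPM in those labelled knockout. Means were 116.4 ± 11.4 (SD, n = 3) and 109.9 ± 1.19 CPM (SD, n = 2). The log2 fold change was 0.08 (SE 0.19, adjusted p = 0.847, edgeR quasi-likelihood test), with a 95% interval of -0.32 to 0.49. Stau1 RNA thus was not detectably lower in the libraries labelled knockout. Counts over all exons of a gene cannot show the loss of part of it, nor the loss of the protein. Groups are therefore named by their labels throughout, and every direction below rests on those labels.

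Myod1, which encodes the muscle-determining transcription factor MyoD, was higher in the libraries labelled wild type. Its level (chromosome 7, 46376474 to 46379092, plus strand, mm10) was 809 ± 141 CPM (SD, n = 3) there and 378.7 ± 110.9 CPM (SD, n = 2) in those labelled knockout, a 2.14-fold difference. The single libraries had 954.4, 800.5 and 672.0 CPM against 300.2 and 457.1 CPM, which rest on 98672, 26322 and 47698 counts and on 2867 and 1437 counts. The log2 fold change was 1.10 (SE 0.22, adjusted p = 0.0252, edgeR quasi-likelihood test), higher in 3 of 3 libraries. The call was lost without wild type 1 (log2 fold change 0.96, adjusted p = 0.0821), without wild type 3 (1.21, adjusted p = 0.0555) and without knockout 1 (0.82, adjusted p = 0.111), all by the same edgeR test.

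**Figure D1:**
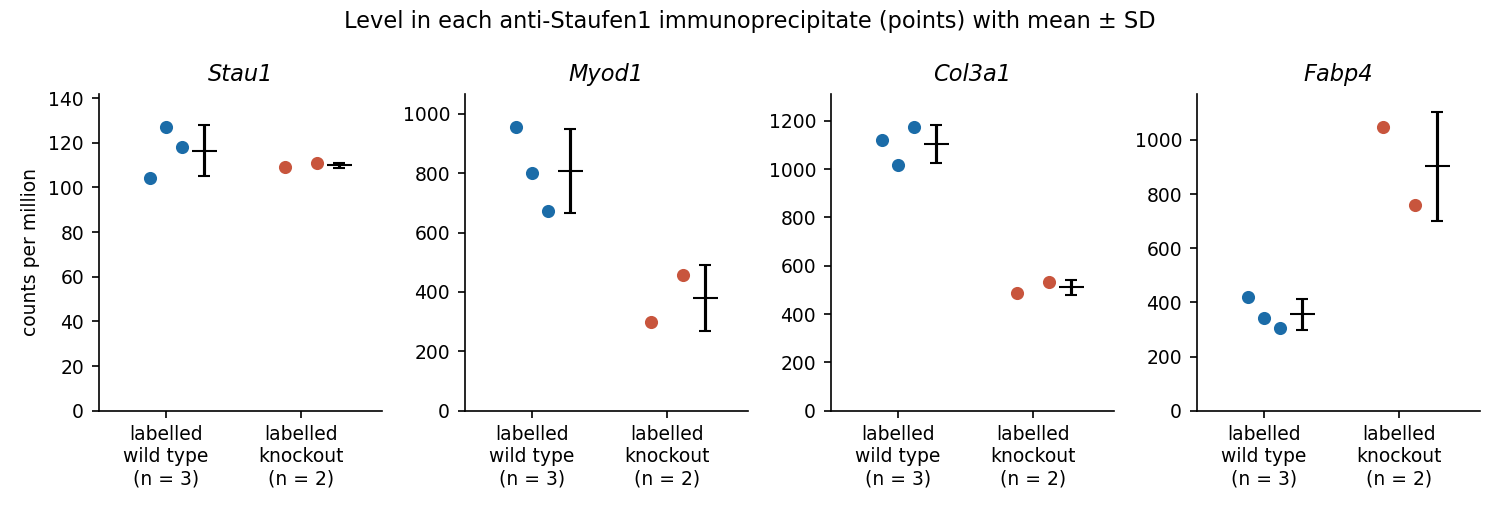
CPM (vertical axis, from 0) of Stau1, Myod1, Col3a1 and Fabp4 in each library; points are libraries labelled wild type (blue, n = 3) or knockout (red, n = 2), and bars are mean ± SD. Stau1 overlapped between the groups, whereas Myod1 and Col3a1 were higher in every library labelled wild type and Fabp4 in every library labelled knockout.

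Across the 11194 genes tested, 118 were higher in the libraries labelled wild type and 112 in those labelled knockout, at an adjusted p under 0.05 in edgeR's quasi-likelihood test. 86 and 98 of them differed by more than 2-fold, and their median absolute log2 fold changes were 1.15 and 1.30. 2286 genes had an unadjusted p under 0.05, where chance gives 560. The groups did not overlap for 118 of 118 and 111 of 112 called genes, against 38.4% of all genes and 20% by chance. A call itself favours genes whose groups lie apart, so the values of the called genes add no separate support. With total counts in place of TMM factors, 93 genes were higher in the libraries labelled wild type and 143 in those labelled knockout, a wild type share of 39.4% in place of 51.3%. The counts depended on single libraries. The count higher in wild type was 21 without wild type 1, 11 without wild type 3 and 64 without knockout 2. The count higher in knockout was 40 without wild type 1, 23 without wild type 3 and 172 without wild type 2.

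**Figure D2:**
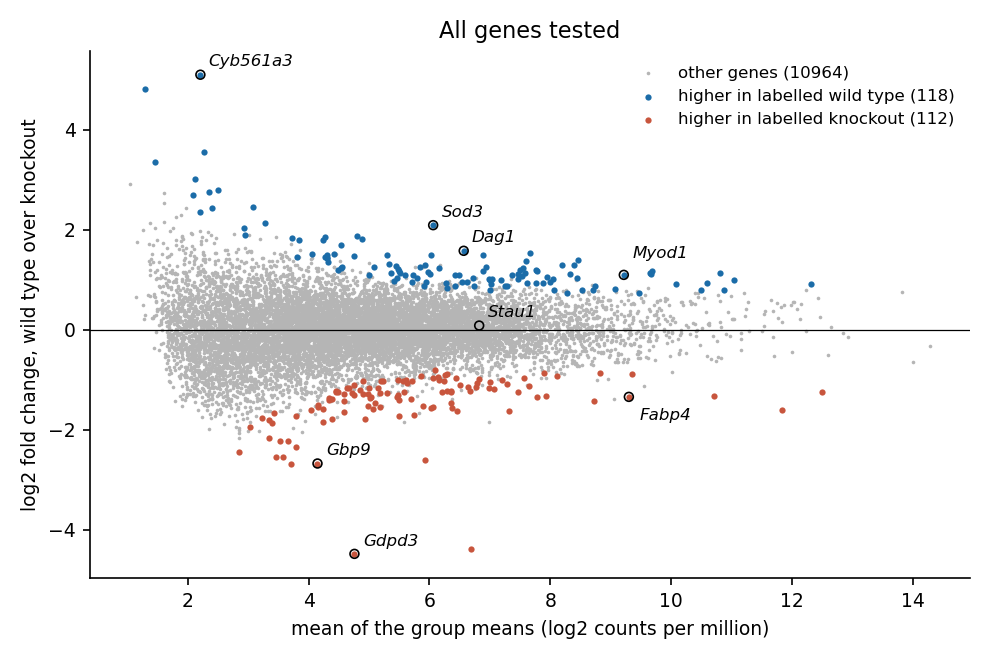
Log2 fold change, wild type over knockout (vertical axis), against the mean of both group means in log2 CPM (horizontal axis), one point per gene; blue and red points passed an adjusted p of 0.05. The 118 and 112 called genes lie above and below 0, Myod1 and Fabp4 among them, and Stau1 lies near 0.

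The largest difference among the named genes higher in the libraries labelled wild type was that of Cyb561a3, a cytochrome b561 family reductase, with 8.89 ± 2.75 (SD, n = 3) against 0.370 ± 0.376 CPM (SD, n = 2). It had 1970 counts over the wild type libraries and 3 over the knockout libraries, a ratio of 39.1 with a 95% counting interval of 13.4 to 190. Lrrn1, a leucine-rich repeat membrane protein, rested on 1740 and 8 counts (ratio 12.9, interval 6.56 to 30), and Ephx3, an epoxide hydrolase, on 932 and 6 counts (ratio 9.25, interval 4.23 to 25.3). Sod3, the secreted superoxide dismutase, was the best measured, with 108.3 ± 17.8 against 25.2 ± 2.39 CPM, a log2 fold change of 2.09 (SE 0.23) and an edgeR adjusted p of 0.00207. The other 8 were Pamr1, Srpx, Alg9 (a mannosyltransferase of N-glycan assembly), Mir6358, Idua (the lysosomal alpha-L-iduronidase), Yod1 (a deubiquitinase), Tbx4 (a T-box transcription factor of the hindlimb) and Fam117b, with log2 fold changes from 2.14 for Fam117b to 3.01 for Pamr1; that of Idua, 2.45, was 4.53 without knockout 1. Idua overlaps Dgkq and Slc26a1, and Yod1 overlaps Pfkfb2, so that their reads may be shared. Mir6358 is a microRNA entry of 101 bases, so its reads, from oligo(dT)-primed RNA, may belong to a longer transcript there. The rule takes only genes whose libraries do not overlap between groups, so a direction kept with a library left out follows from that choice. All 12 kept their direction with each library left out, but Cyb561a3 and Sod3 were the only ones called every time. With all libraries, the calls of Srpx, Alg9 and Tbx4 were lost with RLE factors and with total counts, those of Srpx and Tbx4 also with upper-quartile factors, those of Srpx and Fam117b with limma-voom, and those of Ephx3, Srpx, Mir6358 and Idua after thinning. As few as 2 of the 12 were called without wild type 1 or without wild type 3, 3 without knockout 1, 5 without knockout 2 and 8 without wild type 2, with adjusted p up to 0.194.

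Among the named genes higher in the libraries labelled knockout, Gdpd3, a lysophospholipase D, had 51.7 ± 48.0 CPM (SD, n = 2) against 2.42 ± 1.55 CPM (SD, n = 3), with 85.7 and 17.8 CPM in knockout 1 and 2. Its log2 fold change was -4.49 (SE 0.57, edgeR adjusted p = 0.00365). Gbp9, an interferon-inducible guanylate-binding protein, had 30.6 ± 5.54 against 4.82 ± 0.741 CPM, with a log2 fold change of -2.68 (SE 0.33) and an edgeR adjusted p of 0.00365. Gbp9 overlaps Gbp4, so reads of the pair may be shared. The other 10 were Btnl9, Pde9a (a cyclic GMP phosphodiesterase), Srpk3 (a muscle-enriched SR protein kinase), Casq1 (the calcium-binding calsequestrin of fast muscle fibres), Tnfrsf10b (a TRAIL receptor), Madd, Peli2 (a Pellino ubiquitin ligase), Me1 (cytosolic malic enzyme), Hacd4 and Ly6k, with log2 fold changes from -1.85 for Ly6k to -2.69 for Btnl9. Without knockout 1, Ly6k was at -1.08 and Gdpd3 at -2.90. Hacd4 overlaps Focad. All 12 kept their direction with each library left out, and Gdpd3 and Gbp9 were called every time. 4 of the 12 were called without wild type 3, 5 without wild type 1 or without knockout 1, 7 without knockout 2 and 9 without wild type 2, with adjusted p up to 0.207. The smallest p of all genes belonged to an unnamed gene model at chromosome 8, 102864779 to 102865853 (minus strand, mm10), which overlaps the pseudogene Gm8730. It had 301.6 and 90.4 CPM in knockout 1 and 2 against 9.48 ± 0.741 CPM in wild type, with a log2 fold change of -4.38 and an edgeR adjusted p of 0.000108; it was chosen after its values were seen.

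Some matrix genes were higher in the libraries labelled wild type. Of 31 members of the extracellular matrix and adhesion list, 10 were higher there, 0 were lower and 21 passed neither way, and the median log2 fold change was 0.68. Adjusted over the list alone, 18 were higher and 1 was lower. Dag1, the dystroglycan precursor that anchors cells to laminin, had 142.6 ± 21.2 (SD, n = 3) against 46.9 ± 16.9 CPM (SD, n = 2), a 2.99-fold difference. The collagen genes Col3a1 (1103 ± 78.8 against 510.6 ± 31.9 CPM, 2.16-fold), Col4a1 (2.24-fold), Col4a2 (2.15-fold), Col1a1 (2.45-fold), Col6a1 (2.01-fold) and Col6a2 (1.92-fold) were called too, as were Sparc (2461 ± 274 against 1119 ± 185 CPM), Lamc1 and Fn1. The list had a camera adjusted p of 4.58e-12 with the preset correlation and an adjusted p of 0.266 with an estimated correlation. Its centred log2 level was 0.33, 0.25 and 0.11 in wild type 1, 3 and 2, the order of depth, and -0.35 and -0.34 in knockout 1 and 2. Dag1 alone among the 10 was called with each library left out; 1 of 10 was called without wild type 3 or without knockout 1, 4 without wild type 1, and 6 without knockout 2. Of 20 markers of fibro-adipogenic progenitors, the collagen-producing cells of muscle, 2 were higher (Col3a1 and Col1a1, both also in the matrix list), 1 was lower (Ly6a, -0.87) and 17 passed neither way. Their median was 0.42 and camera's adjusted p 0.0341, which became an adjusted p of 0.603 with an estimated correlation; adjusted over the list alone, 3 were higher and 2 were lower. The level of this list overlapped between the groups (-0.16 in wild type 2 and -0.06 in knockout 2, centred log2), whereas that of the matrix list did not. None of the 3 genes was called without wild type 3 or without knockout 1. With the preset correlation, the call of the list was lost without wild type 1, without wild type 3 and without knockout 1, where the adjusted p reached 0.216.

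Some genes of the muscle stem cell state were higher in the libraries labelled wild type. In the quiescence list of 31 genes, 4 were higher, 0 were lower and 27 passed neither way, with a median of 0.50; adjusted over the list alone, 11 were higher and 1 was lower. Called members were Gas1, a growth arrest gene (509 ± 89.1 against 192.4 ± 56.6 CPM), Spry1, an inhibitor of receptor tyrosine kinase signalling (419 ± 83.9 against 169.0 ± 56.0 CPM), the syndecan Sdc4 (2016 ± 281 against 1052 ± 115 CPM) and the receptor Fgfr4. Pax7, the defining transcription factor of these cells, had 238.7 ± 26.1 against 216.2 ± 50.2 CPM and a log2 fold change of 0.14 (SE 0.20, edgeR adjusted p = 0.748). The list had a camera adjusted p of 1.03e-07, and an adjusted p of 0.266 with an estimated correlation. None of its 4 calls held without knockout 2, where their adjusted p reached 0.186; 1 held without wild type 1 or without wild type 3, and 2 without knockout 1. Of 18 myogenic regulators, 2 were higher, Myod1 and the repressor Msc (171.6 ± 35.2 against 85.9 ± 6.27 CPM), 0 were lower and 16 passed neither way. Adjusted over the list alone, 3 were higher and 0 lower. The median was 0.25 (0.38 without knockout 1 and 0.16 without knockout 2), the camera adjusted p 0.00957, and the adjusted p 0.325 with an estimated correlation. Neither Myod1 nor Msc was called without wild type 1, without wild type 3 or without knockout 1, and Msc was not called without knockout 2 either (adjusted p up to 0.144).

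In the immediate early gene list of 24, made of transcription factors and regulators induced within minutes of a stimulus, 1 was higher and 23 passed neither way. The called member was Egr1, at 6603 ± 634 (SD, n = 3) against 3508 ± 895 CPM (SD, n = 2). Junb (0.74, adjusted p = 0.0508) and Myc (0.63, adjusted p = 0.0911) did not pass the edgeR test. Adjusted over the list alone, 12 were higher and 0 lower. The median was 0.50 (0.315 without knockout 2), the camera adjusted p 1.45e-06, and the adjusted p 0.325 with an estimated correlation. Of 30 genes of endoplasmic reticulum folding, 1 was higher, the disulfide isomerase Pdia4 (87.6 ± 7.32 against 40.7 ± 4.53 CPM), and 29 passed neither way; the count adjusted over the list alone was 1. The chaperone Hspa5 had a log2 fold change of 0.52 (adjusted p = 0.115). The median was 0.34 (0.215 without wild type 1), the camera adjusted p 0.00157, and the adjusted p 0.375 with an estimated correlation. The Egr1 call was lost without wild type 1, without wild type 3 and without knockout 2 (adjusted p up to 0.158), and the Pdia4 call without wild type 1, without wild type 3 and without knockout 1 (up to 0.0796).

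**Figure D3:**
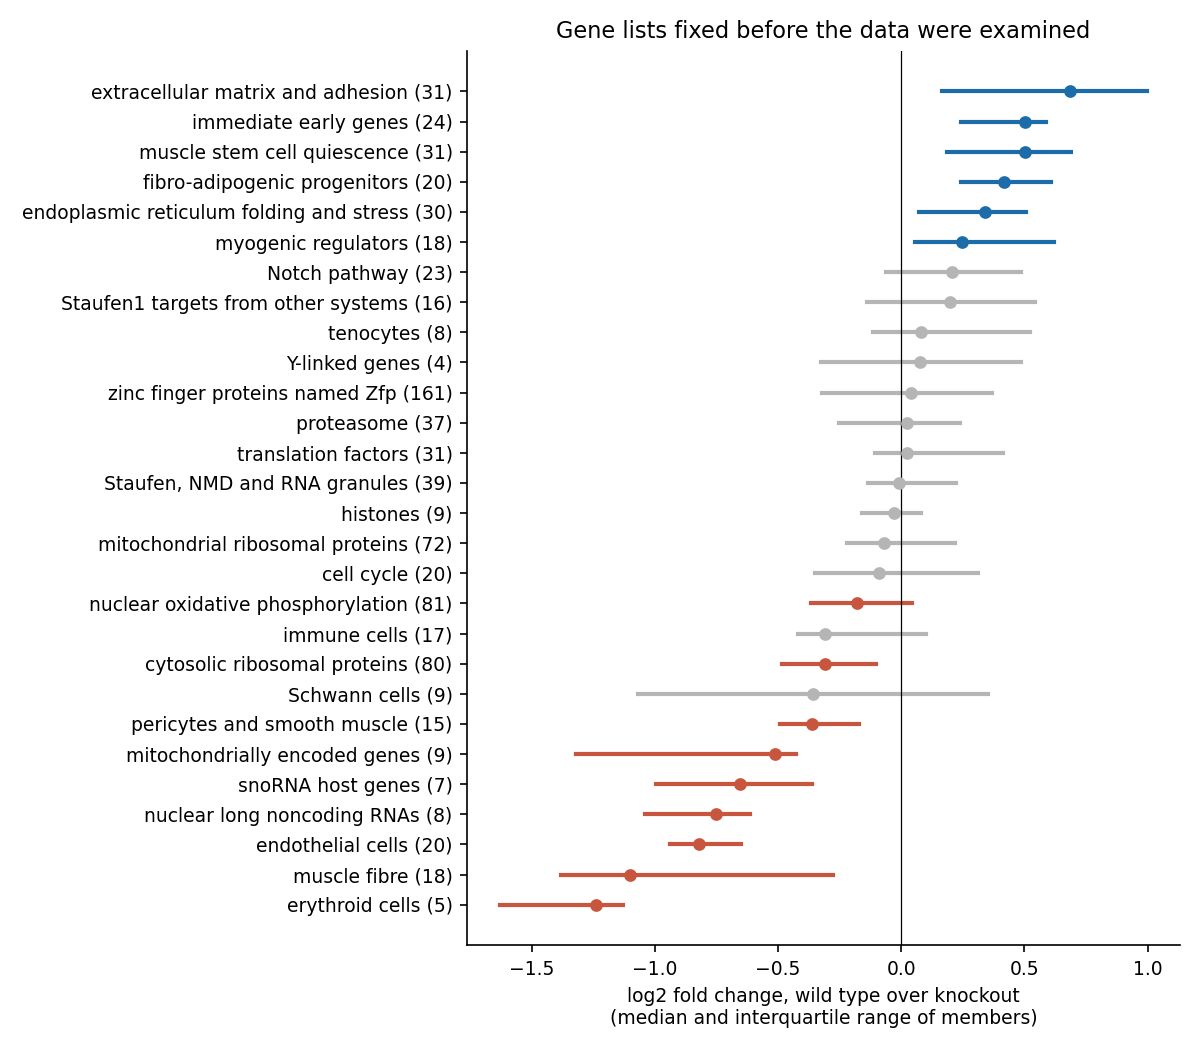
Median (point) and interquartile range (line) of the log2 fold change, wild type over knockout, over the members of 28 gene lists, with the number of genes in brackets; blue and red lists passed camera's adjusted p of 0.05 with the preset correlation, grey lists did not. Of 15 lists that passed, 6 were higher in the libraries labelled wild type and 9 in those labelled knockout. With an estimated correlation 0 passed, in a test that also has fewer degrees of freedom.

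Some endothelial genes were higher in the libraries labelled knockout. Of 20 endothelial markers, 6 were higher there, 0 were lower and 14 passed neither way, with a median log2 fold change of -0.82; adjusted over the list alone, 15 were higher in knockout. Fabp4, a fatty acid binding protein of capillaries, had 902.7 ± 202.3 CPM (SD, n = 2) against 355.8 ± 58.4 CPM (SD, n = 3), a 2.54-fold difference. Egfl7 was 2.13-fold, Emcn 2.05-fold, the VEGF receptor Flt1 1.96-fold, Ly6c1 1.90-fold and the water channel Aqp1 1.85-fold higher. With the preset correlation the camera adjusted p was 3.59e-14, and the adjusted p 0.342 with an estimated correlation. Fabp4 was called with each library left out; 1 of the 6 was called without wild type 3, 2 without knockout 1 or without knockout 2, and 5 without wild type 1 or without wild type 2. Of 5 measured genes of red blood cells, 3 were higher in the libraries labelled knockout and 2 passed neither way, with a median of -1.24. Hbb-b1 (241.2 ± 106.1 against 77.3 ± 13.0 CPM), Hba-a1 (274.7 ± 87.0 against 125.0 ± 18.1 CPM) and Hba-a2 were called, and counting can split reads between these near-identical copies, so their separate values are uncertain; the log2 fold change of Hba-a2, -1.24, was -0.80 without knockout 2. Adjusted over the list alone, 4 were higher in knockout. The camera adjusted p was 1.03e-07, and the adjusted p 0.325 with an estimated correlation. Hbb-b1 was the 1 member called without wild type 3 or without knockout 2.

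Muscle fibre genes had a median of -1.10 over 18 members, of which 0 were called either way; adjusted over the list alone, 8 were higher in knockout and 1 in wild type. Their level was carried by knockout 2. The mean log2 level of the list, centred over the 5 libraries, was 1.20 in knockout 2, -0.50 in knockout 1, and -0.12, -0.24 and -0.34 in wild type 1 to 3. Myl1, a myosin light chain of fast fibres, had 199.6 ± 215.7 CPM in the libraries labelled knockout against 54.6 ± 1.22 CPM (adjusted p = 0.0648). For the list, the camera adjusted p was 0.00174, and the adjusted p 0.549 with an estimated correlation. Without knockout 2 the direction turned, to a median of 0.21 and an adjusted p of 0.0809, and without knockout 1 the median was -1.92. The call was also lost with limma-voom, where the median was -0.45, and the median was -0.59 with the replicate number as a block. Of 15 pericyte and smooth muscle markers 0 were called, with a median of -0.36, and adjusted over the list alone 1 was higher in each direction. The camera adjusted p was 0.0464, and the adjusted p 0.549 with an estimated correlation. That call was lost without wild type 2, wild type 3 or knockout 2 (median -0.14 without knockout 2), with an adjusted p up to 0.317, and also with limma-voom, with the replicate number as a block and after thinning.

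**Figure D4:**
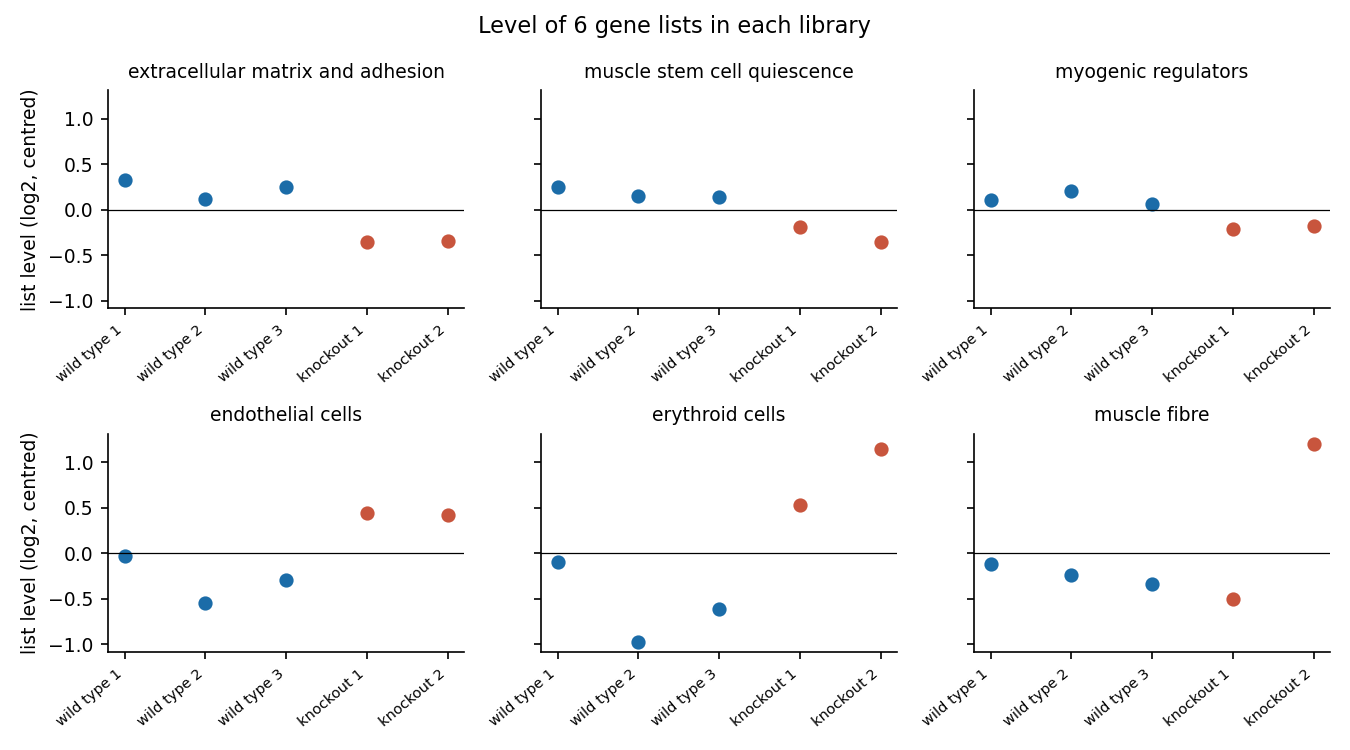
Mean log2 CPM of the members of 6 gene lists in each library, centred on the mean of the 5 libraries (vertical axis, log2); blue points are libraries labelled wild type and red points those labelled knockout. The endothelial list was at 0.45 and 0.43 in the knockout libraries and between -0.55 and -0.03 in the wild type libraries, and the muscle fibre list was raised in knockout 2, at 1.20.

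Of 9 genes on the mitochondrial chromosome, 4 were higher there and 5 passed neither way: gene models over both ribosomal RNAs, ND1 (2382 ± 22.8 against 956.1 ± 286.6 CPM) and COX1 (8117 ± 845 against 3430 ± 1446 CPM), the last being subunits of respiratory complexes. The median was -0.51, the camera adjusted p 3.47e-06, and the adjusted p 0.325 with an estimated correlation; adjusted over the list alone, 7 were higher in knockout and 1 in wild type. ND1 was called with each library left out, and it was the 1 member called without knockout 2; 2 were called without wild type 1 or without wild type 3. All 9 together took 1.93% and 2.11% of counts in knockout 1 and 2, and 0.645%, 1.04% and 1.00% in wild type 1 to 3. Of 81 nuclear genes of oxidative phosphorylation 0 were called, over the list alone as well, with a median of -0.18, a camera adjusted p of 0.0188 and an adjusted p of 0.539 with an estimated correlation. That list was no longer called without knockout 2 (median -0.08, adjusted p = 0.361), and its median was -0.30 without knockout 1. From the deepest to the shallowest library (wild type 1, wild type 3, wild type 2, knockout 1, knockout 2) the level of the mitochondrially encoded list was -0.49, -0.40, 0.01, 0.36 and 0.51, so it followed depth within the wild type group as well.

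The 80 cytosolic ribosomal protein genes had a median of -0.31, with 73 members below 0, but 1 member was called, Rpl12 (580.5 ± 87.8 against 319.8 ± 69.6 CPM), and 0 were called over the list alone. The camera adjusted p was 7.36e-08, and the adjusted p 0.539 with an estimated correlation. The 8 nuclear long noncoding RNAs all lay below 0, with a median of -0.75 and 0 called, and adjusted over the list alone 4 were higher in knockout. Neat1, which scaffolds nuclear paraspeckles, had 583.3 ± 120.3 against 288.2 ± 96.4 CPM (adjusted p = 0.0544). The camera adjusted p was 1.35e-05, and the adjusted p 0.375 with an estimated correlation. Of 7 snoRNA host genes 1 was called, Snhg20 (115.3 ± 34.5 against 49.0 ± 19.3 CPM), and 5 over the list alone, with a median of -0.66, a camera adjusted p of 0.000492 and an adjusted p of 0.375 with an estimated correlation. In the same order of depth the level of the nuclear long noncoding RNAs was -0.82, -0.36, 0.18, 0.45 and 0.56, and that of the snoRNA hosts -0.49, -0.36, 0.05, 0.18 and 0.62, so both differed within the wild type group in the order of depth. The Rpl12 call was lost without wild type 1, wild type 3, knockout 1 or knockout 2 (adjusted p up to 0.188), and the Snhg20 call without wild type 1, wild type 3 or knockout 2 (up to 0.199).

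The remaining 13 lists did not pass camera with the preset correlation. Among 16 Staufen1 targets from other systems, the median was 0.20 (0.08 without knockout 2) and the camera adjusted p 0.14, whereas fry, which asks only whether the members move on balance in 1 direction, gave an adjusted p of 0.0343. The urokinase receptor Plaur was higher in the libraries labelled wild type (200.0 ± 34.1 against 109.6 ± 8.79 CPM, adjusted p = 0.0459, edgeR), a call lost with any library left out except wild type 2 (adjusted p up to 0.163), and with RLE factors or total counts. Adjusted over the list alone, 3 were higher and 1 lower. Among 39 Staufen proteins, decay factors and RNA granule proteins the median was -0.01, 0 were called, over the list alone as well, and the adjusted p was 0.868. The Notch pathway (23 genes) had a median of 0.21 and an adjusted p of 0.0888, translation factors (31) 0.02 and 0.374, and cell cycle genes (20) -0.09 and 0.854. In the cell cycle list Ccnd1, the cyclin D1 gene, was called higher in the libraries labelled wild type (29.2 ± 2.32 against 10.9 ± 4.67 CPM). Immune cell markers (17) had a median of -0.31 (-0.12 without wild type 2 and -0.11 without knockout 2) and an adjusted p of 0.52, and Schwann cell markers (9) -0.36 and 0.0693, with a fry adjusted p of 0.0343 and a median of -0.55 without wild type 1, -0.21 without wild type 2 and -0.64 after thinning. Among the latter Mbp, the myelin basic protein gene, was higher in the libraries labelled knockout (249.2 ± 48.3 against 104.6 ± 10.3 CPM, adjusted p = 0.0105, edgeR) with each library left out. Tenocyte markers (8) had a median of 0.08 and an adjusted p of 0.837, with Mkx called higher in knockout (34.9 ± 6.05 against 13.0 ± 4.03 CPM). Y-linked genes (4) had 0.08 and 0.923, mitochondrial ribosomal proteins (72) -0.07 and 0.868, proteasome genes (37) 0.02 and 0.868, histones (9) -0.03 and 0.709, and zinc finger genes named Zfp (161) 0.04 and 0.868, with Zfp612 called higher in knockout. The Ccnd1 call was lost with any library left out except knockout 1 (adjusted p up to 0.147), and with total counts, upper-quartile factors or limma-voom. The Mkx call was lost without wild type 1, wild type 3 or knockout 2 (up to 0.138), and the Zfp612 call with any library left out (up to 0.102). Adjusted over the list alone, 3 Schwann cell genes, 1 histone and 1 Zfp gene were higher in knockout, 1 cell cycle gene was higher in wild type, and tenocyte markers had 2 higher in wild type and 1 in knockout. The other lists of this paragraph, apart from the Staufen1 targets, had 0. Medians of the translation factor, proteasome and Zfp lists turned to -0.02, -0.02 and -0.00171 with total counts. The cell cycle median turned to 0.12 without knockout 2 and 0.02 with the stricter filter, the histone median to 0.10 without knockout 1, and the tenocyte median to -0.08 without wild type 1, and those of the Staufen protein and Y-linked lists also changed sign with a library left out, so none of these lists has a settled direction. The sign of camera's direction differed from that of the median for the cell cycle, proteasome and Staufen protein lists, and the mean of the mitochondrial ribosomal list was 0.02 against its median of -0.07.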

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

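Thinning was chosen after the data were seen; the other alternatives were fixed beforehand. Counts of genes higher in the libraries labelled wild type, and of those higher in knockout, were 118 and 112. They were 434 and 466 with DESeq2, 411 and 443 with the edgeR exact test, 2 and 6 against a 1.5-fold change, and 161 and 178 after thinning every library to the shallowest, where 105 and 102 of the genes were the same. Leaving out each library gave 11 to 176 genes higher in wild type and 23 to 172 higher in knockout. The lowest counts came without wild type 3, and 64 were higher in wild type without knockout 2. Other scalings and limma-voom gave 93 to 106 and 105 to 143, and the stricter filter 124 and 118. Dropping the filter changed nothing, since it removed no gene. The replicate number as a block gave 288 and 324 genes, of which 118 and 108 were among those called without it, and 14 lists. Only 2 numbers occur in both groups, and the deviations of same-numbered libraries correlated at 0.05 and 0.04 across genes. The deviations of 2 knockout libraries mirror each other, so these values cannot show whether same-numbered libraries were paired. Myod1 kept its direction with a library left out (0.82 to 1.43) and in the 10 other settings in which its value was recomputed (1.05 to 1.24), and its call in all of these but the 3 leave-outs named with its values; the test against a 1.5-fold change was read only as a count of genes. Stau1 was never called (adjusted p 0.791 to 0.969 with a library left out). Of 28 lists, 15 passed camera with the preset correlation, 0 with an estimated one, 6 with fry in 1 direction (myogenic regulators, quiescence, immediate early genes, extracellular matrix, Staufen1 targets from other systems and Schwann cells) and 12 to 14 with a library left out. The muscle fibre list reversed without knockout 2, with an adjusted p of 0.0809 there and as low as 2.23e-31 over the other leave-outs. Its members Mylpf (log2 fold change from -2.69 to 0.0136) and Myl1 (from -2.69 to 0.21) did so too. Across the named genes, 154 results under an alternative lost their call, 120 gained one and 2 reversed. The cause of these changes was not tested, except that a left-out library leaves fewer samples. Where a knockout library is left out, the lone remaining one is assumed to vary like the wild type libraries. Depth limits the libraries labelled knockout most: 522 genes had under 10 counts in knockout 2.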

Other observations

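Of the tests below, those on the explanations and on the 4 added gene lists, and the bounds that decide them, were chosen after the results they bear on had been seen; the count over splits of the libraries was not. Bootstrap intervals below were drawn over the genes of a list. Such genes can vary together in a library, so these intervals leave out the spread between libraries. The 9 genes of this paragraph lie outside the fixed lists and were chosen after their values were seen, so they stand for no group. Bmp6, a bone morphogenetic protein, had 96.2 ± 12.6 CPM (SD, n = 3) against 33.99 ± 1.42 CPM (SD, n = 2), Tnfaip6, a hyaluronan-binding protein, 299.5 ± 66.8 against 104.4 ± 18.8 CPM, and the chemokine Ccl2 175.5 ± 58.1 against 62.2 ± 2.43 CPM. Tgfb2 was 2.81-fold, the latent TGF-beta binding protein Ltbp1 2.04-fold, and the collagen chaperone Serpinh1 2.19-fold higher. In the other direction, the adenylate cyclase Adcy4 (2.95-fold), Ushbp1 (2.98-fold) and the class I histocompatibility gene H2-Q8 (2.55-fold) were higher in the libraries labelled knockout. All passed an adjusted p of 0.05 in edgeR's quasi-likelihood test. With each library left out, Bmp6, Tnfaip6, Adcy4 and Ushbp1 were called every time; 5 of the 9 were called without knockout 1, 7 without wild type 3 or without knockout 2, and 8 without wild type 1, with adjusted p up to 0.0861.

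Gbp9 and its overlapping neighbour Gbp4, both interferon-inducible, prompted a test of 33 other interferon-inducible genes. Their median log2 fold change was -0.578 (95% bootstrap interval -0.908 to -0.258). The upper bound was -0.415 in each of 10 repeats of the resampling, so the printed -0.258 was not reproduced. Of these genes, 29 of 33 lay below 0, and 3 were called higher in the libraries labelled knockout: Bst2, Gbp7 and Isg15. The camera adjusted p over the 4 added lists was 2.14e-09, and the adjusted p 0.0833 with an estimated correlation. Knockout 1 carried more of it than knockout 2, with centred list levels of 0.58 and 0.12; without knockout 1 the median was -0.31. None of the 3 calls held without wild type 3 or without knockout 1 (adjusted p up to 0.233), and only Bst2 held without wild type 1 or without wild type 2. No input RNA was used here, so cell state and antibody recovery stay open.

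Of 20 endothelial transcripts, 6 were called higher in the libraries labelled knockout (median -0.82, adjusted p 0.342 with an estimated correlation). A smaller share of stem cells, with the mix of other cells unchanged, would raise the markers of every other cell type alike. The endothelial median minus that of fibro-adipogenic markers without collagens was -1.23 (95% bootstrap interval over genes -1.38 to -0.889). The difference in their levels was -0.35 or lower in every wild type library and 0.42 or higher in both knockout libraries. If both marker sets were recovered alike in the groups, this argues against a smaller share with an unchanged mix of other cells. Recovery was not measured apart, and a smaller share with a changed mix was not tested. Thinning keeps the share of every gene, so the endothelial median after it, -0.826 (interval -0.894 to -0.722), decides nothing, and depth and genotype cannot be told apart, since both knockout libraries are shallower than all wild type libraries. Within the wild type group the endothelial level ran the other way, from -0.03 in the deepest library to -0.30 and -0.55 in the shallower ones, but 3 libraries are too few to exclude depth. A second list of 23 endothelial genes, with 4 called (0 of them without wild type 3 or without knockout 1), had a median of -0.739 (interval -1 to -0.456), as more endothelial RNA in the preparations labelled knockout would give, so RNA from endothelial cells may be a candidate source. In knockout the most abundant genes of the first list were Fabp4, Aqp1 and Gpihbp1, at 902.7, 847.1 and 388.2 CPM, and those of the second were Tm4sf1 and Cav1, at 361.1 and 356.5 CPM, whose log2 fold changes were -0.57 and -0.03, so Cav1 did not move with the others. Antibody recovery that differs with genotype is the biological explanation the design gives. CPM values are shares of a library, so transcripts recovered more in wild type could by themselves raise the share of others in knockout. This explanation stays open, since no input RNA was used here. The labels describe no sort that would show the share of endothelial cells.

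Myod1 and 4 of 31 quiescence genes were called higher in the libraries labelled wild type, while Pax7 was not. The 3 called among 16 identity genes (Msc, Fgfr4 and Sdc4) add no further gene to those called in the quiescence and myogenic lists, and 0 of them held without wild type 1, wild type 3, knockout 1 or knockout 2 (adjusted p up to 0.186). The quiescence and identity lists did not pass with an estimated correlation (adjusted p 0.266 and 0.0833). A larger share of stem cells, with the mix of other cells unchanged, would lower all other markers there alike. The endothelial, erythroid, fibre, pericyte, Schwann and immune medians were lower, whereas those of tenocytes (0.08) and fibro-adipogenic progenitors (0.42) were not. The fibre median turned to 0.21 without knockout 2, and the immune list had a camera adjusted p of 0.52. The endothelial level minus that of fibro-adipogenic markers without collagens was 0.769 higher in the lowest knockout library than in the highest wild type library. Its widest range within a group was 0.402. If both marker sets were recovered alike in the groups, this argues against a larger share with an unchanged mix of other cells. It does not argue against one with a changed mix, and recovery was not measured apart. The gap is the one used above for the endothelial transcripts, so it is no separate test. The level of those fibro-adipogenic markers itself overlapped between the groups (-0.20 in wild type 2 and 0.0045 in knockout 2). Within the wild type group it fell in the order of depth, from 0.35 to 0.22 and -0.20. Myod1 after thinning, at 1.07 (95% interval 0.60 to 1.54), decides nothing for the same reason as above, and depth cannot be told apart from genotype. Dilution of stem cell RNA by RNA of other cells could lower all stem cell transcripts by 1 factor. The median of 16 identity genes, of which 11 are also in the quiescence list, was 0.543 (95% bootstrap interval 0.399 to 0.752) against a lower 95% bound of 0.62 for Myod1, so for the list as a set dilution and a difference specific to Myod1 cannot be told apart: the intervals overlap and 2 knockout libraries give little precision. Pax7, with a 95% interval of -0.29 to 0.57, lay below the interval of Myod1 with all libraries. The difference between these 2 genes was not tested, and Myod1 was at 0.82 without knockout 1. Whether 1 factor covers both genes is therefore not settled. Recovery with Staufen1 stays open as the explanation that the design gives, and Stau1 RNA, alike in both groups, does not help to decide.

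Of 31 matrix transcripts, 10 were called higher in the libraries labelled wild type (median 0.68, adjusted p 0.266 with an estimated correlation). At the lengths of the matrix genes, a trend on gene length over all other genes gives a median of -0.0134 (95% bootstrap interval -0.0211 to -0.00833), which argues against length as the whole cause. The matrix median exceeded that of fibro-adipogenic markers without collagens by 0.276 (interval -0.081 to 0.612), so RNA from those cells cannot be told apart from another cause, the interval being too wide. Genes of collagen modification and secretion, 27 in all, with Colgalt1 the 1 called (lost with any library left out except wild type 2, adjusted p up to 0.0863), had a median of 0.456 (interval 0.387 to 0.773, 23 of 27 above 0, camera adjusted p of 5e-06 over the 4 added lists and an adjusted p of 0.0833 with an estimated correlation), the direction of the matrix genes. Within the wild type group the matrix level fell in the order of depth, from 0.33 to 0.25 and 0.11. That of the collagen modification list fell likewise, from 0.30 to 0.20 and 0.11. Depth and genotype cannot be told apart here either. Whether transcripts of secreted proteins are bound by Staufen1 stays open.

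The 5 libraries can be split into 3 and 2 in 10 ways, too few for a share under 0.05. The real split called 230 genes, the highest of the others 0, and 1 of the 10 splits, the real one, reached 230. Every other split mixes both labels within a group, so any difference between the labels widens the spread there and lowers the count. The real split also parts the deeper from the shallower libraries, so the contrast does not tell genotype from depth.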
